A study of Magallana gigas with 60 samples.

How the data were processed

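Gill of Pacific oysters from 4 families was sampled before heat shock (0 h) and 1, 3, 6 and 24 h after it. Each of the 20 combinations of family and time had 3 arrays, 60 in all. Per the labels, heat shock was at 40 °C for 1 hour, each sample held 50 mg of gill from several individuals, and RNA was amplified, labelled with Cy3 and mixed with 4 RNA standards. The labels do not say which families survived heat shock better, so family was a factor of 4 levels and all 3 ways of setting a pair of families against the other pair were tested.

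The deposited scanner files give, per the file headers, spot intensity, local background and background standard deviation of 1 channel for 30000 spots, with no background subtraction. The authors also deposited a table of natural log values for 3362 spots. Each of its columns correlated with intensity minus background of the same array at 0.9997 or more, and its column medians ran from 6.83 to 7.55. What set its scaling factor and the constant it subtracted is not recorded in the deposited files. The table was used only as an alternative.

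Spot intensities were corrected with normexp (offset 50), quantile normalized between arrays, taken to log2 and averaged over the 4 spots of each feature, with limma 3.58.1 in R 4.3.3. Control features (251) were left out of the tests, which left 7165 features, called ESTs here and numbered by the position of their first spot. The files describe 1794 of them by gene ontology terms and no gene names, and the other 5371 only by plate and well, so no gene is named. The filter fixed beforehand, signal over local background by 2 background standard deviations on all 3 arrays of a group, removed 0 features, because printed and empty spots alike lay above local background. The precision of the arrays is limited by their number and by the level of empty features: between 17.1% and 90.9% of ESTs per array exceeded the 95th percentile of the 156 empty features.

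limma was fitted to the 20 group means, with empirical Bayes moderation two-sided tests and Benjamini-Hochberg adjustment over all 7165 ESTs at 0.05. Tests covered each later time against 0 h, any change over time, any difference among families, the 3 family contrasts and the family by time interaction. The p-values measure the spread between pooled samples of these 4 families. Gene lists were tested with limma's camera (preset correlation 0.01, and beside it an estimated one), adjusted over lists and times. The design, the alternatives, 18 lists and the rule for naming ESTs were fixed before the data were examined. The lists were heat shock proteins, other protein folding, antioxidant and detoxification, lipid metabolism, immune defence, ribosomal proteins and translation, mitochondrial respiration, glycolysis and energy storage, ubiquitin and proteasome, apoptosis and cell death, extracellular matrix, cilia and tubulin, muscle, hemocyte, gonad and digestive gland markers, signalling and transcription, and the families of genes the study had picked on these samples. The gonad words matched the term "binding" and so 649 ESTs, which makes that list void. Because the words had been written for protein names, 11 lists of ontology terms, one of them a corrected gonad list, were added after the annotation text was seen. The contrast of 24 h with 6 h, the limit from empty features, and the removal of doubtful arrays were added after the data were seen.

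The ESTs ranked were the 1509 described ones whose terms went beyond common cell locations, protein binding and unknown, called annotated here. Other described ESTs were not ranked, also where they passed. Per time, the rule named the 8 annotated ESTs with the largest rise and the 8 with the largest fall. These were taken from those past the threshold with 1 sign in all 4 families. It named the 20 annotated ESTs with the smallest p among families and the 15 with the smallest p for the interaction, where past the threshold. It also named up to 4 members per list past the threshold, all members of the heat shock and study lists, and at most 2 rising and 2 falling ESTs without description per contrast. ESTs of the same description counted once.

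The same fits were explored on the measured data before they were tested on simulated data with known changes. The interaction fell short of the recovery required of the other tests at the largest simulated change and was then exempted from that requirement. For 24 h against 0 h, 38.8%, 86.6% and 98.5% of simulated changes of 0.5, 1 and 2 log2 units were recovered. For the interaction, with the change placed in family 6 at 6 h only, 0%, 3% and 62.1% were. Alternatives covered background correction, normalization, filter, the authors' table, averaging, threshold, test, array weights, the replicate block, scan day, slide series, scanner file kind, and leaving out replicates, single arrays, families and times. Scan days were read from the file headers and numbered 1 to 6. For other splits of the samples, time labels were permuted within families, or family labels within times, for 100 splits with the real one included.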

Results

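Transcript levels were measured in gill of 4 families of Pacific oyster, families 6, 10, 25 and 55, before a heat shock and 1, 3, 6 and 24 h after it. There were 3 arrays for each family and time, so 12 arrays per time and 15 per family. Median spot intensity ran from 275 to 1157 across the 60 arrays, over a median local background of 145 to 194 and a median of empty features of 217 to 854. Levels correlated across ESTs between arrays of a group at 0.878 to 0.977 (median 0.934). Between arrays of different groups they did so at 0.804 to 0.997 (median 0.9285), so replicates were hardly more alike than other arrays. After normalization the 4 RNA standards, added at 100, 10, 1 and 0.1 ng, averaged 14.41, 13.22, 11.49 and 8.0 log2 units. Their SDs over the 60 arrays were 0.29, 0.29, 0.36 and 0.33, against 0.57, 0.70, 0.80 and 0.65 before normalization. The levels rose less from 10 to 100 ng than from 0.1 to 1 ng, so folds between bright levels may be low estimates.

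The first question was which transcripts changed with time after heat shock. At 1 h, 26 of the 7165 ESTs were higher and 1 was lower than before. The described EST among them, EST 13985, carries the terms response to unfolded protein and regulation of translational initiation. It was 0.76 ± 0.18 log2 units higher (SE, n = 12 arrays per time, limma adjusted p = 0.0358), on 11 of 12 arrays, and lost its call in 11 of 24 alternatives. ESTs 2244 and 6006, which the files do not describe, had the largest rises, 3.49 ± 0.32 and 3.44 ± 0.32 log2 units, or 11.3-fold and 10.8-fold. EST 4115, also undescribed, was the 1 that fell, by 1.03 ± 0.16. All 27 changed in the same direction in all 4 families, as did 56 of 56 at 3 h, 107 of 109 at 6 h and 208 of 221 at 24 h. These ESTs were called on the mean over the same 4 families, which favours such agreement, so it is not independent evidence of a shared response. Without family 55, 17 ESTs passed at 1 h.

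At 3 h, 52 ESTs were higher and 4 were lower. The largest rises with a description were those of a cytoskeletal EST and of ESTs annotated to protein folding, unfolded protein binding or the response to unfolded protein. EST 4383, annotated to spectrin binding and epithelial cell polarity, was 4.71-fold higher (2.23 ± 0.36 log2 units, adjusted p = 3.82e-05). EST 9409, with the same terms as EST 13985, was 4.13-fold higher (2.05 ± 0.30). EST 1264, annotated to unfolded protein binding, TPR domain binding and nitric-oxide synthase regulation, was 3.27-fold higher (1.71 ± 0.21). EST 8163, annotated to chaperone cofactor dependent protein folding, was 2.36-fold higher (1.24 ± 0.24). ESTs 4219, 6509 and 766, annotated to transcription, embryonic development and cytochrome-c oxidase, rose by 1.03 ± 0.25, 0.80 ± 0.14 and 0.78 ± 0.16 log2 units. EST 6509 exceeded the limit of empty features on 1 of 12 arrays before heat shock, so its changes are low estimates. The undescribed ESTs 5649 and 4179 rose 14.9-fold and 14.1-fold, for EST 5649 with 10 of its 48 spots at the scanner's upper limit. ESTs 2548 and 966 fell by 1.13 ± 0.28 and 1.05 ± 0.19. EST 2548 lost its call in 10 of 24 alternatives, and the fall of EST 966 is a low estimate, since it exceeded that limit on 8 of 12 arrays at 3 h. A pair of the 3 h arrays, replicate 3 of family 10 and replicate 3 of family 25, correlated across ESTs at 0.997, against at most 0.977 for any other pair. Without both arrays 50 ESTs differed at 3 h.

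At 6 h, 80 ESTs were higher and 29 were lower. EST 1264 was 4.37-fold higher (2.13 ± 0.21 log2 units, adjusted p = 1.87e-10), EST 9409 3.90-fold, EST 4383 3.58-fold and EST 8163 3.28-fold, each on all 12 arrays. EST 766 was 2.56-fold higher, EST 1651, annotated to the large ribosomal subunit, 2.48-fold, EST 4219 2.36-fold and EST 6509 2.12-fold. Among annotated ESTs with 1 sign in all 4 families, the largest fall was that of EST 14395, at -1.11 ± 0.22 (adjusted p = 0.000917). It is annotated to the COPI coat, which carries cargo from the Golgi to the endoplasmic reticulum. EST 11913, annotated to mitochondrial protein import, changed by -0.96 ± 0.23 and EST 8811, annotated to trypsin activity, by -0.89 ± 0.24. Smaller falls were those of ESTs 8792 (RNA polymerase, -0.84 ± 0.22), 7546 (splicing, -0.75 ± 0.21), 14438 (transcription corepressor, -0.70 ± 0.17) and 692 (nucleotide binding, -0.68 ± 0.18). The falls of ESTs 8811, 8792, 7546, 14438 and 692 lost their calls in 11, 7, 13, 6 and 6 of 24 alternatives. The undescribed EST 13933 was 23.4-fold higher. Without family 25, 62 ESTs passed. With other scalings the falls were fewer: 66 rose and 6 fell with median scaling, 79 and 23 with cyclic loess, and 67 and 9 when scaled to the RNA standards. In the authors' table, where only 1500 ESTs could be tested, 54 rose and 8 fell.

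At 24 h, 108 ESTs were higher and 113 were lower. EST 1264 was 5.55-fold higher (2.47 ± 0.21 log2 units, adjusted p = 1.75e-12), EST 8163 3.69-fold (1.88 ± 0.24) and EST 9409 3.21-fold (1.68 ± 0.30), each on 12 of 12 arrays. EST 1264 had 3, 11 and 22 of its 48 spots at the scanner's upper limit at 3, 6 and 24 h, EST 8163 had 5, 10 and 11, and EST 9409 had 2 at 24 h, so their folds at these times are low estimates. Of 67 ESTs of lipid metabolism 3 passed: EST 10641, annotated to cholesterol metabolism and steroid hydroxylase activity, rose by 1.42 ± 0.39 and EST 44, annotated to triacylglycerol lipase activity, by 1.08 ± 0.30, while EST 5042, annotated to lipoxygenase activity, changed by -1.25 ± 0.23. ESTs 8167 (transcription factor activity), 3163 (plasma membrane protein binding) and 9381 (aspartic endopeptidase) rose by 1.24 ± 0.24, 1.15 ± 0.23 and 0.93 ± 0.15. Among annotated ESTs with 1 sign in all 4 families, the largest fall was that of EST 11980 (translation factor, -1.25 ± 0.34). It was above the limit of empty features on 7 of 12 arrays before and 3 of 12 at 24 h. ESTs 5680 (nucleoplasm), 5014 (vesicle transport), 13165 (phosphatase, glycogen metabolism), 8811 (trypsin), 14598 (tubulin) and 1284 (ubiquinol-cytochrome-c reductase) changed by -1.13 ± 0.23, -1.04 ± 0.25, -0.95 ± 0.21, -0.84 ± 0.24, -0.70 ± 0.17 and -0.67 ± 0.17. The calls of ESTs 10641, 44, 8811 and 1284 were lost in 6, 7, 9 and 6 alternatives. The undescribed EST 5046 was 37.2-fold higher, a low estimate, since it exceeded the limit of empty features on 8 of 12 arrays before heat shock, as did ESTs 13985, 766 and 9381. The split depended on the scaling: 80 rose and 51 fell with median scaling, 123 and 76 with cyclic loess, and 70 and 34 when scaled to the RNA standards. In the authors' table, with 1500 ESTs tested, 77 rose and 46 fell.

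**Figure D1:**
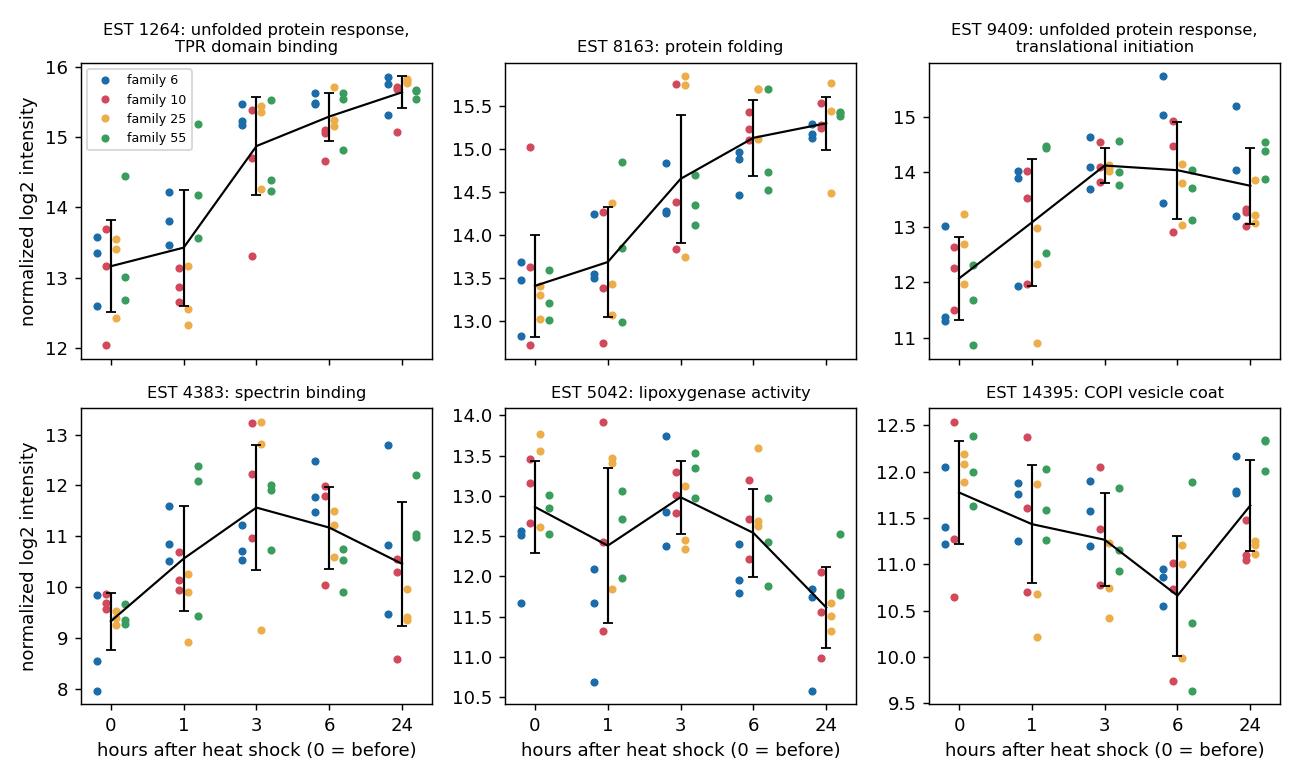
Normalized log2 intensity (vertical axes) of 6 named ESTs against hours after heat shock (horizontal axes, evenly spaced). Points are single arrays coloured by family, and lines with bars are means and SDs of the 12 arrays per time. EST 1264 averaged 13.16 before heat shock and 15.63 at 24 h.

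**Figure D2:**
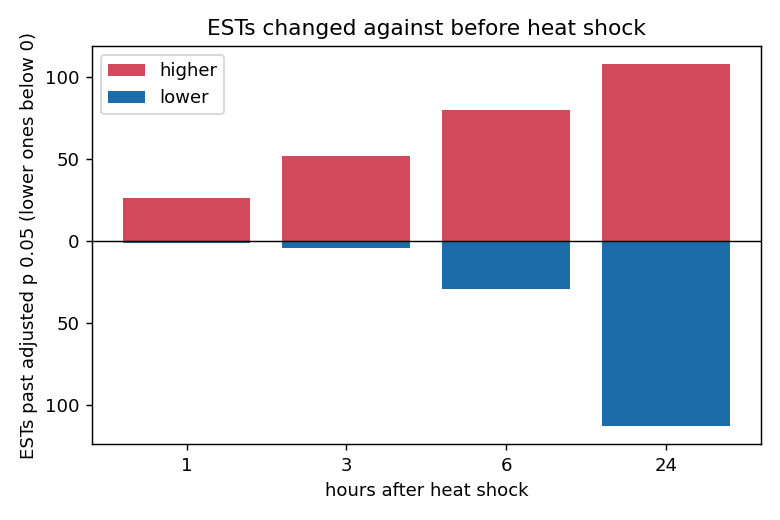
Numbers of ESTs past the threshold at each time against before heat shock (vertical axis), with higher ESTs above 0 and lower ESTs below it. Higher ESTs numbered 26, 52, 80 and 108, and lower ones 1, 4, 29 and 113.

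In all, 273 ESTs changed over time in any way, against 167 with median scaling, 249 with cyclic loess and 149 when scaled to the RNA standards. In the authors' table, where only 1500 ESTs could be tested, 159 did. With scan day as a block the numbers were 27 at 1 h, 71 at 3 h (58 higher, 13 lower), 92 at 6 h (65 and 27), 250 at 24 h (110 and 140) and 290 in any way. With array weights 73 were higher and 18 lower at 3 h, and 163 and 184 at 24 h. Within the scan days that held both times, the share of called ESTs with the same direction was between 96.3% and 100% at 1 h, 98.2% and 100% at 3 h, 97.2% and 99.1% at 6 h, and 91.9% and 97.3% at 24 h, for ESTs chosen on the same arrays. When the ESTs for 24 h were instead called without the arrays of a scan day, 73.6% to 93.7% of them had the same direction on that day (5 days). Scan day 5 held no 24 h array, scan day 6 no 6 h array and scan day 2 no 1 h array.

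None of the 18 planned lists shifted at any time (72 tests, smallest adjusted p = 0.685, camera, 0 also with an estimated correlation, 3 at an unadjusted p under 0.05). At 24 h, 1 of 19 ESTs of other protein folding rose (EST 8163), 2 of 67 of lipid metabolism rose and 1 fell, and 2 of 14 of glycolysis and energy storage fell (EST 13165 and the arginine kinase EST 1473, -0.63 ± 0.18, above the limit of empty features on 6 of 12 arrays at 24 h). Of 32 ESTs of mitochondrial respiration 1 fell, of 33 of translation 1 rose (EST 7506, annotated as lysine-tRNA ligase, 0.91 ± 0.23), of 28 of ubiquitin and proteasome 1 rose (EST 2058, 0.76 ± 0.21, above the limit of empty features on 1 of 12 arrays before heat shock), and of 60 of apoptosis 1 rose (EST 9385, 0.91 ± 0.21) and 1 fell. Of 263 ESTs of signalling and transcription 2 rose (ESTs 8167 and 9500) and 4 fell. None of 41 antioxidant, 26 immune or 12 extracellular matrix ESTs passed. Among markers of cell types, 1 of 20 cilia and tubulin ESTs rose and 1 fell, 1 of 15 digestive gland ESTs fell, and none of 41 muscle or 8 hemocyte ESTs passed. The void gonad list had 7 that rose and 8 that fell of 649, and its corrected form 0 and 1 of 29. Adjusted over the list alone, 3 lipid, 2 respiration, 3 cilia, 1 hemocyte, 5 signalling and 14 void-list ESTs passed at 24 h, and the counts of the other planned lists were as given. The glycolysis list had a mean of -0.11 and a median of 0.02 at 24 h.

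The 4 ESTs described as heat shock proteins (3318, 7036, 8891 and 10766) did not pass at any time. At 24 h they stood at 0.25 ± 0.14, -0.09 ± 0.14, 0.01 ± 0.13 and -0.15 ± 0.14 log2 units, with levels between 7.01 and 7.60 before heat shock. They exceeded the limit of empty features on 3, 6, 0 and 6 of 12 arrays before heat shock and on 3, 2, 1 and 2 at 24 h, so changes in them were hard to detect here. Nor do they stand for every EST that may encode such a protein. ESTs 9409 and 13985, which rose, share all terms of EST 10766 but heat shock protein activity. Among the added lists, protein folding and response to heat (36 ESTs) was higher than other ESTs at 3 h and 24 h (adjusted p = 0.0253 at each). With an estimated correlation adjusted p = 0.367 at both times. Of its members 4 rose at each of these times, ESTs 1264, 8163, 9409 and 13985, and none fell. Its mean change was 0.19 at 3 h and 0.24 at 24 h, against a median of 0.03 and 0.06. At 6 h, when 4 members rose and 1 fell, its adjusted p was 0.213, or 0.445 with an estimated correlation. With scan day as a block adjusted p = 0.00423 at 3 h, 0.00368 at 6 h and 0.00108 at 24 h with the preset correlation, and 0.189 at each with an estimated one. Within scan days the list's mean exceeded that of other ESTs by 0.13 to 0.24 at 3 h on 6 of 6 days, by 0.11 to 0.29 at 6 h on 5 of 5 and by 0.08 to 0.77 at 24 h on 5 of 5. The days are parts of the same arrays that singled out this list, so this is not independent evidence. The other 10 added lists did not shift. At 24 h, 1 of 60 immune and defence ESTs rose (EST 10129, an immune receptor, 0.84 ± 0.16) and 1 fell, 1 of 30 electron transport ESTs rose and 2 fell, 1 of 34 proteolysis ESTs rose and 1 fell, and 2 of 80 cell cycle ESTs rose and 1 fell. None of 26 reactive oxygen, 118 ribosome, 16 protease inhibitor or 20 RNA processing ESTs passed at 24 h, and 1 of 27 extracellular matrix ESTs fell (EST 13823, -0.60 ± 0.17, above the limit of empty features on 5 of 12 arrays at 24 h).

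The next question was how the families differed. Levels of 39 ESTs differed among the 4 families, 4 of them annotated with a function. The count was 20 with median scaling, 39 with cyclic loess and 10 when scaled to the RNA standards. In the authors' table, with 1500 ESTs tested, it was 14. EST 6948 (GTPase activity) was 1.09 ± 0.15 log2 units higher in family 25 than in family 55 (adjusted p = 8.31e-06, n = 15 arrays each), a low estimate, since it exceeded the limit of empty features on 4 of 15 arrays of family 55. EST 7530 (collagenase activity) was highest in family 10 and lowest in family 55, 1.09 ± 0.19 apart (adjusted p = 0.000751). It fell in the list of the study's own genes, chosen on these samples, by a match of words at their start only. The word collagen would match collagenase too, so whether the study picked this EST is not known. It is not independent evidence. The other members of that list, the collagen ESTs 5253, 5728 and 14013, had adjusted p = 0.83, 0.89 and 0.85. EST 8180 (transcriptional activator) differed by 1.13 ± 0.26 between families 10 and 55, and EST 8404 (small ribosomal subunit) by 0.53 ± 0.11 between families 6 and 55, with its call lost in 6 alternatives.

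Of the 3 ways to pair the families, 20 ESTs differed in mean between families 6 and 55 and families 10 and 25 (10 higher, 10 lower). Between families 6 and 25 and families 10 and 55, 13 did (7 higher, 6 lower). Between families 6 and 10 and families 25 and 55, 4 did (3 higher, 1 lower). The pairings share ESTs, and a single odd family can make an EST pass. The undescribed EST 1282 averaged 11.89, 11.58 and 11.80 in families 6, 10 and 25 and 9.61 in family 55, and passed in all 3 pairings. In the order 20, 13 and 4, the counts were 13, 6 and 0 with median scaling, 25, 12 and 9 with cyclic loess, and 9, 6 and 2 when scaled to the RNA standards. In the authors' table, with 1500 ESTs tested, they were 8, 12 and 0. The count of 4 moved by more than 1.5 times without some single arrays, between 2 and 10. The undescribed ESTs 11014 and 2222 were 4.62 ± 0.19 and 4.30 ± 0.20 log2 units higher in families 6 and 55. These are low estimates, since in families 10 and 25 EST 11014 exceeded the limit of empty features on 4 and 3 of 15 arrays and EST 2222 on 10 and 4. Their means were 12.12 and 12.16 in family 6, and 7.80 and 8.17 in family 10. On replicate 2 of family 55 before heat shock they stood at 7.65 and 7.32. EST 3947 differed the other way, by -1.80 ± 0.15, and exceeded that limit on 7 of 15 arrays in each of families 6 and 55, EST 12943 was 2.03 ± 0.16 lower in family 55 than in family 25, and EST 5968 was 1.85 ± 0.14 higher in family 55 than in family 6. With scan day as a block the numbers were 47 among families and 7, 19 and 23 for the 3 pairings in the order 4, 13 and 20. Within scan days, 95% to 100% of the called ESTs, which were chosen on the same arrays, kept their direction. Families were not balanced over scan days: scan day 3 held 0 arrays of family 10 and 6 of family 55.

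**Figure D3:**
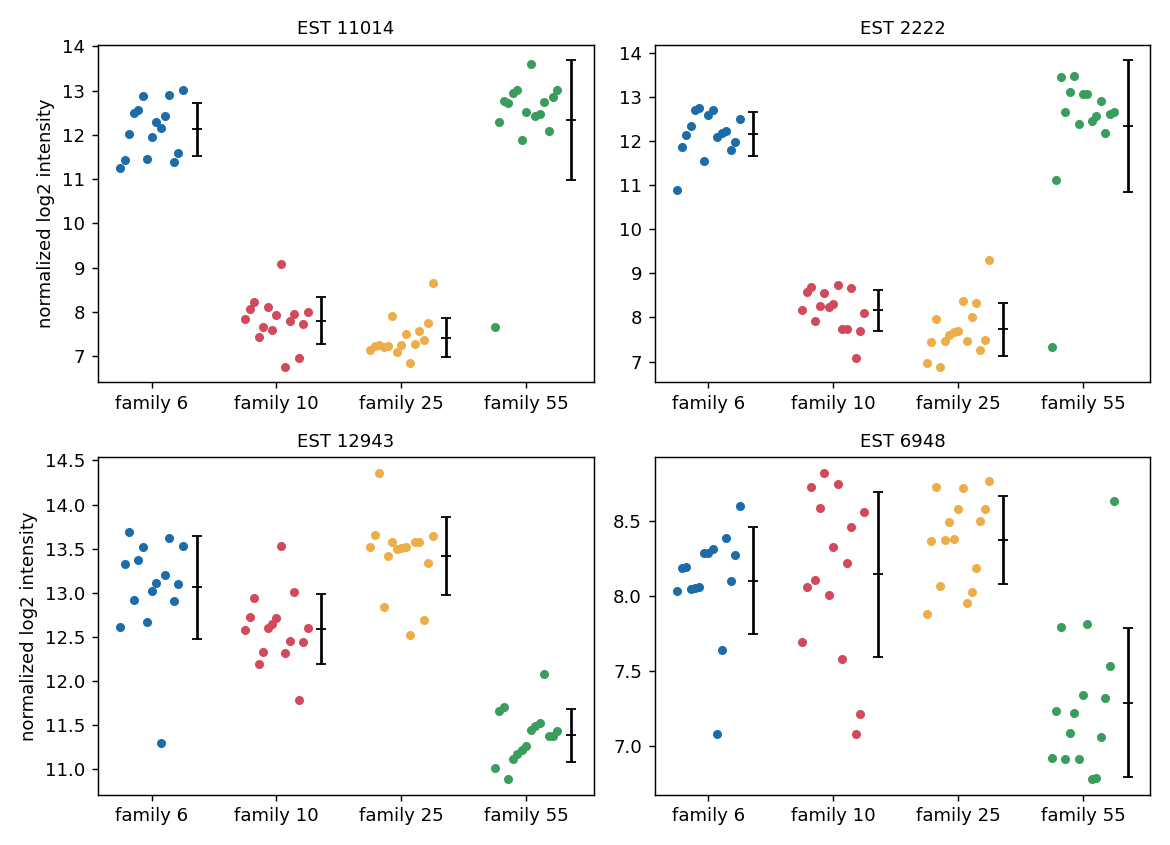
Normalized log2 intensity (vertical axes) of 4 ESTs in each family. Points are the 15 arrays of a family in order of time, and the marks beside them are the mean and SD. For EST 11014, 1 array of family 55 lay at 7.65, near the levels of families 10 and 25.

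Whether families differed in their response to heat shock was tested by the interaction of family and time. With limma 0 of 7165 ESTs passed, 271 had an unadjusted p under 0.05, and the ordinary analysis of variance also gave 0. In simulated data the change was placed in a single family at a single time. Of such changes of 1 and 2 log2 units, 3% and 62.1% were recovered. Differences of 1 log2 unit confined in this way were therefore hardly detectable here. Recovery of differences that span several times or several families was not simulated, so the limit for them is not known.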

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

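No result met the criteria set for a closer look: groups of 3 arrays are too small for the test of outlying samples, 0 of the 53 named ESTs differed among families in their time course, and 0 of the 87 control features of other species exceeded the empty-feature limit on all 60 arrays. On at least 30 arrays, a count made after the values were seen, 9 of 37 white spot virus features and 1 of 34 catfish features did. For the pair of alike arrays, all tests were chosen only after the result was seen, as were the test of a mislabelled or mixed sample and the tests of scan day and of quantile normalization for the time changes. The test of 24 h against 6 h and the added lists were not planned.

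Time labels were permuted within families for 100 splits, the real one included. For 1, 3, 6 and 24 h against 0 h, any time and 24 h against 6 h, 1 of the 100 splits gave as many ESTs, the real one. The real counts were 27, 56, 109, 221, 273 and 152, and the highest others 2, 1, 6, 1, 2 and 1, so chance can be excluded for these counts. With family labels permuted within times, 1 split gave as many as the 39 ESTs among families (highest other 4). For the pairings with 4, 13 and 20 ESTs, 2 of 100 splits each gave as many, the real one included, which met the bound of fewer than 5 of 100. The highest others, 9, 25 and 49, exceeded the real counts, and what set those splits apart was not tested. The bound was not adjusted for the 3 pairings, so chance is not excluded for these counts. The permutation also removes every difference among families, so a single odd family can pass it without a difference between pairs. For the interaction (highest other 24) and the planned lists (highest other 2) the real count was 0, which all 100 splits meet by construction, so the splits say nothing about them. For the added lists 5 of 100 splits gave as many as the 2 real shifts, with a highest other of 3, so chance cannot be excluded for the folding list.

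The arrays labelled family 10 and family 25, replicate 3 at 3 h, were nearly alike. Deviations of single spots from their feature's mean, which belong to a slide, correlated at 0.928 between them and at most at 0.488 between any other pair, so both labels may hold a single slide. A shared scan day is argued against, since other pairs of a day had a median of 0.163. On 9 ESTs that part the families, with family 10 at 0 and family 25 at 1, the pair lay at 0.920, while the other arrays of family 10 reached at most 0.400 and those of family 25 began at 0.611. This argues against family 10 RNA on that slide. Local background correlated at 0.949 between the pair, against at most 0.818 for other pairs, while 8 of 30000 spots had identical intensities, so the files are not copies of each other. No biological explanation was tested.

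ESTs 11014 and 2222 stood near the level of empty features on replicate 2 of family 55 before heat shock, with differences of -4.88 and -4.96 log2 units from the other replicates of that group. Neighbouring features on that array were not dim, with a median difference of 0.370 over 8 features, and of the 7 other arrays of families 6 and 55 of that scan day 0 were low, which argues against dim spots and scan day. On 16 other ESTs that part family 55 (at 1) from the rest (at 0), the array lay at 0.805, above every array of another family (at most 0.445) but below the other family 55 arrays (at least 0.857), which argues against RNA of another family as the cause of the low levels. To lower them this far, 96.6% of the RNA for EST 11014 and 96.8% for EST 2222 would have to come from families 10 and 25, and a mixture with 96.6% would lie at -0.0115. A difference between the pooled individuals of the family stays open and was not tested.

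For the ESTs changed after heat shock, scan day was not balanced over the times. The count over time was 290 with scan day as a block and 273 without, and of the ESTs called at 24 h without the arrays of a scan day 87.3% (median day) had the same direction on that day, which argues against scan day as the whole cause. A first test of quantile normalization, that called ESTs keep their direction when scaled to the RNA standards (100% did), said nothing, because that scaling moved the median of all ESTs too little to turn them. A second one, set after that, compared sizes: the median rises and falls at 6 h and 24 h kept 0.960 or more of their size. The same small move, with the median of all ESTs at -0.059 at 6 h and 0.003 at 24 h, largely fixed this outcome beforehand. It therefore does not decide whether quantile normalization was a cause, and shows only that sizes were alike under both scalings. Of the falls, 9 of 29 at 6 h and 34 of 113 at 24 h stayed past the threshold, as their median SE grew from 0.18 to 0.23 and 0.24. A response to heat shock stays open as a hypothesis, since no unheated gill was sampled at the later times and handling or time of day cannot be told apart from it.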

How the results depend on the processing

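No named EST changed sign in the 24 alternatives run for single ESTs, of which the authors' values covered 50 of 70 tests and the limit to ESTs in their table covered 57. Named ESTs were not run without single arrays, families or times. The balance of rises and falls turned for some counts. Of 1060 alternative counts, 952 stayed within 1.5 times the count reported, 88 were lower and 20 higher. Most of these left out a single array of 60, and counts that stayed at 0 were taken as unchanged, so these shares do not measure stability. Without 1 replicate number of every group, the counts at 24 h, over time, among families and for 24 h against 6 h moved beyond 1.5 times in 3 of 3 settings each. Those at 1, 3 and 6 h did so in 1 of 3 each. Of 1647 alternative values of single ESTs, 1478 kept their call and 169 lost it, and of 81 values of the added lists 62 stayed and 19 were weaker. The filter on local background and the one on detection in part of all arrays moved nothing, because all spots of the features lay above local background, and they say nothing about stability. The contrast of 24 h with 6 h, the limit and background from empty features and the removal of doubtful arrays were chosen after seeing the data. Dim ESTs were limited by the empty features, which a median of 59.2% of ESTs per array exceeded. The cause was not tested for any of the values below, except that fewer arrays, fewer ESTs and a stricter threshold allow fewer calls by construction.

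Pairings 1, 2 and 3 stand here for families 6 and 10, 6 and 25, and 6 and 55 against the others. With median scaling there were 72 ESTs at 6 h, 131 at 24 h, 167 over time, 20 among families, 0, 6 and 13 in the pairings, and 84 between 24 h and 6 h. Scaled to the RNA standards there were 104 at 24 h, 149 over time, 10 among families, 2, 6 and 9 in the pairings and 75 between 24 h and 6 h. In the authors' values only 1500 ESTs could be tested. There were 62 at 6 h, 123 at 24 h, 159 over time, 14 among families, 0 and 8 in pairings 1 and 3, and 93 between 24 h and 6 h. That table left the median of all ESTs at 0.11 at 1 h and at -0.12 for 24 h against 6 h. Cyclic loess gave 9 in pairing 1. The ESTs of that table alone gave 22 among families. The share that rose moved from 53.8% to 83.3%, 66.7% and 41.7% in pairing 2 and from 50% to 38.5%, 33.3% and 25% in pairing 3 with median scaling, RNA standards and the authors' values. It moved from 75% to 88.9% with cyclic loess and 50% with the standards in pairing 1, and from 54.6% to 40.5% with median scaling for 24 h against 6 h.

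At an adjusted p of 0.01 there were 72 at 6 h, 134 at 24 h, 23 among families, 2, 8 and 13 in the pairings and 97 between 24 h and 6 h. Array weights gave 91 at 3 h, 347 at 24 h, 440 over time, 98 among families and 14, 42 and 50 in the pairings. Pairing of samples by replicate number was neither shown nor excluded: residuals correlated at 0.00742 within a number and at -0.00375 between numbers (permutation p = 0.184), and 28 of 60 arrays had their best match in their own number, against a mean of 20.01 with permuted numbers (permutation p = 0.053). The replicate block gave 2 in pairing 1 and 228 at 24 h. Scan day as a block gave 7 in pairing 1 and 233 between 24 h and 6 h, and scanner file kind 2 in pairing 1.

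Without family 25 there were 62 at 6 h, and without family 55, 17 at 1 h and 99 between 24 h and 6 h. Among families there were 18, 23 and 20 without 0 h, 3 h and 24 h. Pairing 1 gave 1, 1 and 2 without 1 h, 3 h and 6 h. Pairing 2 gave 7, 7 and 3 without 0 h, 3 h and 24 h, and pairing 3 gave 13 without 1 h and 13 without 3 h. Without both alike arrays pairing 1 gave 2, and without the one labelled family 25 it gave 7.

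Leaving out single arrays, or 1 replicate number of every group, gave 17 to 28 at 1 h, 37 to 66 at 3 h, 55 to 115 at 6 h, 109 to 236 at 24 h and 150 to 290 over time. It gave 10 to 50 among families, 1 to 10, 2 to 19 and 6 to 29 in the pairings, and 69 to 157 between 24 h and 6 h. The interaction stayed at 0. For the planned lists, which were run without each replicate number but not without single arrays, the count was 0.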

Other observations

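The comparison of 24 h with 6 h after heat shock was chosen after the data were seen. Between these times 83 ESTs were higher and 69 lower at 24 h. The split depended on the scaling, with 34 higher and 50 lower with median scaling, 94 and 55 with cyclic loess, and 38 and 37 when scaled to the RNA standards. In the authors' table, with 1500 ESTs tested, 50 were higher and 43 lower. Some ESTs that had fallen at 6 h were higher again: EST 14395 of the COPI coat by 0.97 ± 0.22 log2 units and EST 692 (nucleotide binding) by 1.08 ± 0.18 (SE, n = 12 arrays per time). ESTs 9395 (helicase), 8167 (transcription factor), 7506 (lysine-tRNA ligase), 13813 (semaphorin receptor) and 6883 (cystine transport) were 1.11 ± 0.22, 1.08 ± 0.24, 0.99 ± 0.23, 0.95 ± 0.23 and 0.91 ± 0.26 higher. EST 2538, without a known process, was 1.74 ± 0.34 higher. ESTs 5042 (lipoxygenase), 4219 (transcription), 6509 (embryonic development), 8178 (receptor kinase) and 2382 (RAB GTPase) differed by -0.93 ± 0.23, -0.92 ± 0.25, -0.85 ± 0.14, -0.84 ± 0.20 and -0.62 ± 0.17. The undescribed ESTs 2244 and 6006, which had the largest rises at 1 h, stood at 12.77 and 12.03 at 6 h and at 9.36 and 8.64 at 24 h, and ESTs 5046 and 10678 were 4.57 ± 0.27 and 2.83 ± 0.23 higher at 24 h. Within scan days holding both times, 92.8% to 100% of the called ESTs, which were chosen on the same arrays, kept their direction, and with scan day as a block 233 passed.

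Of the 108 ESTs that rose at 24 h, 32 were undescribed ESTs with the plate prefix CG_HCI. Such ESTs made up 7.58% of tested ESTs (Fisher's exact test, two-sided, adjusted p = 3.41e-10 over all prefixes and times). Of the 26 that rose at 1 h, 12 came from plates with the prefix CVG_MIX (13.4% of tested ESTs, Fisher's exact test, adjusted p = 0.00129), and that prefix also held more of the rises than of the tested ESTs at 3 and 6 h (adjusted p = 0.0233 at each). The prefix CG_SSH (3.39% of tested ESTs) gave 8 of 52 rises at 3 h, 9 of 80 at 6 h and 11 of 108 at 24 h (adjusted p = 0.00559, 0.0126 and 0.0107). At 24 h CV_UNI, CV_EMB and PkMr gave 2, 1 and 0 of the 108 rises, with 11.04%, 7.29% and 5.36% of tested ESTs (adjusted p = 0.007, 0.0233 and 0.0233). At 1 h 1 of 26 rises was a described EST (25.0% of tested ESTs, adjusted p = 0.0498). Described ESTs carry no plate name, so the counts and shares of every prefix cover undescribed ESTs only. What the prefixes stand for is not recorded in the deposited files. These tests were chosen after seeing the data and treat ESTs as independent.

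The 26 ESTs that rose at 1 h may include several copies of a single transcript. Their deviations from the group means correlated with a median of 0.211, against at most 0.122 in 100 random sets of ESTs, but separate transcripts regulated together would give the same.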
